A study of Mus musculus with 26 samples.

How the data were processed

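The values used were read counts per gene in 26 poly(A) RNA-seq libraries, deposited by the authors as tables of whole numbers, 1 column per library and 1 line per gene. The submitters' notes give alignment to mm10 with STAR 2.6.1c. Of the 2 tables, the first holds 24 of the libraries, and 0 values differed between the tables where both hold a library. The tables hold 24411 gene symbols, of which 0 are duplicated. A further 4 columns carry names that match no sample label and were not used. The strand setting of the counting is not given in the sources used here, and the labels name either a directional NEBNext Ultra kit or the UltraII kit without saying which was used for a library. Values of genes that overlap another gene on the opposite strand, such as Ppp1r3fos, are therefore uncertain, and so are the values of close paralogs (Gbp2b, Gbp2 and Gbp11, the H2 genes and the Klr genes), between which reads can be shared.

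Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by the edgeR expression filter, which left 12227 genes for testing and removed 12184. The tested genes held at least 99.9% of the reads of every library. Libraries were scaled by TMM, and a robust quasi-likelihood model with 1 coefficient for each of the 13 groups of 2 libraries was fitted to all 26 libraries, with 13 residual degrees of freedom. Its common dispersion was 0.0147 and the median prior degrees of freedom were 5.13. Each comparison was a contrast of that model, and a gene counted as called at an edgeR adjusted p (Benjamini-Hochberg over all tested genes) below 0.05. Differences between comparisons were contrasts of the same model, with the same threshold. Expression values are TMM-scaled CPM (read counts scaled to a common library size), given as the mean ± SD of 2 libraries, and log2 fold changes are given ± SE. That SE is approximate, being the absolute log2 change divided by the square root of its F statistic. The p-values rest on a spread estimated over all 26 libraries, and measure only the spread between these samples. The labels do not say whether the libraries of a group come from separate animals. Within WT Treg, BATFKO Treg and Tconv, libraries differed by a chi-square per degree of freedom of 22.7, 29.9 and 21.7. Other groups had 3.00 to 7.79, so p-values of comparisons of WT Treg, BATFKO Treg and Tconv may be too small. Where that variation is shared by libraries with the same number, they may instead be too large. The labels state no such pairing, and it was not part of the model.

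Where a group had 0 reads for a gene, the fold is given as a lower bound against a floor of 3 counts over the group. Where a group had 1 to 3 reads, the ratio of counts is given with its 95% exact interval. Both cover counting error only, since reads from PCR-amplified libraries are not independent molecules.

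The groups, the comparisons, the lists of known genes, the alternatives and the rule for naming genes were chosen before the data were examined. Foxp3 and Batf are always named. In the 4 mutant comparisons, and in eTreg against cTreg, eTreg against Teff and cTreg against Tnaive, the 8 called genes with the largest log2 fold change in each direction are named, and 5 in each direction in the others. Such a gene needed a mean of at least 5 CPM in the higher group, with both libraries of 1 group above both of the other (not asked of differences between comparisons). Immunoglobulin and T cell receptor segments, mitochondrial genes and predicted gene models were not named. From each list of known genes, up to 4 called members with the smallest p are named, and up to 3 uncalled members where a sentence is about the list. Genes outside the rule are said to have been chosen after their values were seen. Positions are whole gene spans on mm10 from the GENCODE M21 annotation, whose symbols matched 11760 of the 12227 tested genes.

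The 19 lists of known genes were Treg core, effector Treg, suppressor molecules, naive and central T cell, bZIP and IRF factors, Th1, Th2, Th17, Tfh, cytokines, chemokine receptors and integrins, TCR signalling and immediate early genes, cell cycle, interferon response, B cell, myeloid and dendritic, CD8 and NK, and erythroid markers, and dissociation stress. They were written from general knowledge of these cells, and some genes sit in several of them. A further 2 lists, of plasmacytoid dendritic and of B cell genes, served a test in the closing section only. The sorted wild-type populations, which share no library with the mutant comparisons, gave 4 more lists. The eTreg-high list holds 1444 genes called at least 2-fold higher in eTreg than in cTreg, and the cTreg-high list 485 genes called at least 2-fold lower. The Treg-high list holds 228 genes called at least 2-fold higher both in cTreg than in Tnaive and in eTreg than in Teff, and the Treg-low list 101 genes lower in both. Batf and Foxp3 were left out of these 4, whereas Foxp3 stayed in the Treg core list and Batf in the list of bZIP and IRF factors. Lists were tested with camera against the other tested genes, at a preset inter-gene correlation of 0.01, and adjusted over 171 tests of known lists and over 16 tests of lists from the sorted populations. Of the 171 tests, 101 passed at the preset correlation and 65 with a correlation estimated from the data. Where a list named in a mutant comparison passed at the preset but not at the estimated correlation, the latter value is printed. List medians were also computed with genes at 0 reads in a group set to their bound. This moved 24 of 187 medians by over 0.1, by up to 3.52 for the cytokine list in Teff against Tnaive, and such medians are given at the bound. The heat map of list medians and the medians of differences between comparisons use fitted values throughout.

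Recovery was measured on counts drawn for the tested genes from the observed group means, dispersions and library sizes, with a known set of genes changed in each comparison. The dispersion of a gene was the same in all groups, and only genes above a minimum expression in the reference group were changed. In the BATFKO comparison 91% of genes changed 4-fold and 71% of genes changed 2-fold were called, and 5.26% of the calls were false. The corresponding shares were 93%, 70% and 4.12% for BATFcKO, 90%, 76% and 2.35% for Foxp3R397W, 98%, 84% and 7.14% for Foxp3KO, and 97%, 66% and 3.55% for eTreg against cTreg. These shares hold under the fitted model only. They do not measure the false share among the real BATFKO calls, whose libraries varied more within groups than the model assumes.

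The alternatives were no expression filter, a filter of at least 5 CPM in 2 libraries, RLE scaling, the DESeq2 Wald test, a model of the libraries of a comparison alone, a block for the library number, calls of at least 2-fold only, the estimated inter-gene correlation, and leaving out each library in turn. When a library was left out, its group kept 1 library, which was assumed to vary like the other groups. A further 3 were added after the data had been seen. They were camera tests on differences between Foxp3 and BATF comparisons, the Foxp3KO set thinned to the depth of the Foxp3R397W set, and counts without Teff-specific genes. Isoforms, alignments and chromatin data were not analysed here. A few genes that the naming rule selects are not reported here.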

Results

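Poly(A) RNA was sequenced from CD4+ T cells sorted freshly from lymph nodes and spleen of C57BL6/J mice, in 13 groups of 2 libraries each. Regulatory T cells (Treg) were recognised by a human CD2 (hCD2) or YFP reporter expressed with Foxp3, the transcription factor that defines the lineage. BATF is an AP-1 family factor that acts with IRF4 in effector T cells. Germline BATFKO Treg and their wild-type (WT) Treg were CD4+hCD2+ cells, and CD4+hCD2- conventional T cells (Tconv) belonged to the same set. The title of the Tconv libraries names Tconv while their cell type label reads Treg with an hCD2- gate, and they were grouped by title. BATFcKO Treg YFP, in which Foxp3-driven Cre deletes a floxed Batf, and WT Treg YFP were CD4+YFP+hCD2- cells. Foxp3R397W Treg, with a missense change in the DNA-binding domain of Foxp3, and Foxp3KO Treg were hCD2+GFP- cells from mice with 2 reporter-tagged Foxp3 alleles, each with its own WT control from the same gate. From WT mice, central Treg (cTreg; hCD2+, gated among other markers as CCR7 high and CD44 low), effector Treg (eTreg; hCD2+, gated among other markers as CCR7 low), naive conventional (Tnaive) and effector conventional (Teff) cells were sorted with the corresponding gates.

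Library totals in the germline set were 7171323 and 6243918 counts in WT Treg, 7300917 and 6268841 in BATFKO Treg, and 5615929 and 6504506 in Tconv. WT Treg YFP held 6813077 and 6023008 and BATFcKO Treg YFP 5790232 and 6181035 counts. The Foxp3R397W libraries held 6036966 and 6831764 and their controls 6398174 and 6117078. Sorted cTreg (10641332 and 10002374), eTreg (10005091 and 9915735), Tnaive (9774025 and 9886572) and Teff (9780591 and 10392428) were deeper, and deepest were Foxp3KO Treg (33568216 and 34613707) and their controls (26321134 and 31456198). The correlation of log CPM between the libraries of a group ran from 0.973 to 0.996 across genes, which are not independent replicates. The Foxp3KO set and its controls lay apart from all other libraries on the second principal component (52.1 to 66.6, against at most 12.5), so values were compared only within a set. Jun differed between library numbers in the germline set. Its CPM was 1179 in WT Treg 1, 769.1 in BATFKO Treg 1 and 1180 in Tconv 1, but 2295, 1942 and 2202 in the libraries numbered 2.

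Batf (chromosome 12, 85686669 to 85709087) was expressed in every WT population. It stood at 131 ± 27.9 CPM in eTreg and 34.1 ± 1.19 in cTreg (log2 change 1.94 ± 0.27, edgeR adjusted p = 1.6e-05), and at 86.4 ± 24.1 in Teff and 32.8 ± 0.17 in Tnaive (1.40 ± 0.27, edgeR adjusted p = 0.00042). Germline BATFKO Treg retained 7.02 ± 0.273 CPM against 64.5 ± 26.1 in WT Treg (-3.19 ± 0.33, edgeR adjusted p = 1.7e-05). BATFcKO Treg YFP retained 17.7 ± 2.52 against 63.1 ± 6.64 (-1.84 ± 0.30, edgeR adjusted p = 0.0019). Foxp3 mutants were not called for Batf, with 39.3 ± 9.97 against 52.9 ± 4.65 CPM in Foxp3R397W (-0.43 ± 0.28, edgeR adjusted p = 0.52) and 52.3 ± 5.17 against 79.0 ± 9.45 in Foxp3KO (-0.60 ± 0.25, edgeR adjusted p = 0.19). Transcript from outside a deleted part still counts towards Batf, so these values do not measure the loss of protein.

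Foxp3 (chromosome X, 7573644 to 7595245) stood at 530 ± 14.6 CPM in cTreg and 503 ± 26.5 in eTreg, against 2.77 ± 0.603 in Tnaive, 0.283 ± 0.0138 in Teff and 3.32 ± 1.06 in Tconv. BATF loss did not change it detectably. It was 491 ± 118 in BATFKO against 455 ± 71.2 CPM in WT Treg (0.11 ± 0.15, edgeR adjusted p = 0.93), and 764 ± 29.3 in BATFcKO against 772 ± 52.4 in WT Treg YFP (-0.02 ± 0.15, edgeR adjusted p = 0.99). No change was called in Foxp3R397W Treg, at 351 ± 11.7 against 416 ± 51.6 CPM (-0.25 ± 0.15, edgeR adjusted p = 0.48). In Foxp3KO Treg the Foxp3 transcript fell to 111 ± 3.05 from 337 ± 16.1 CPM (-1.60 ± 0.15, edgeR adjusted p = 2e-06).

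**Figure D1:**
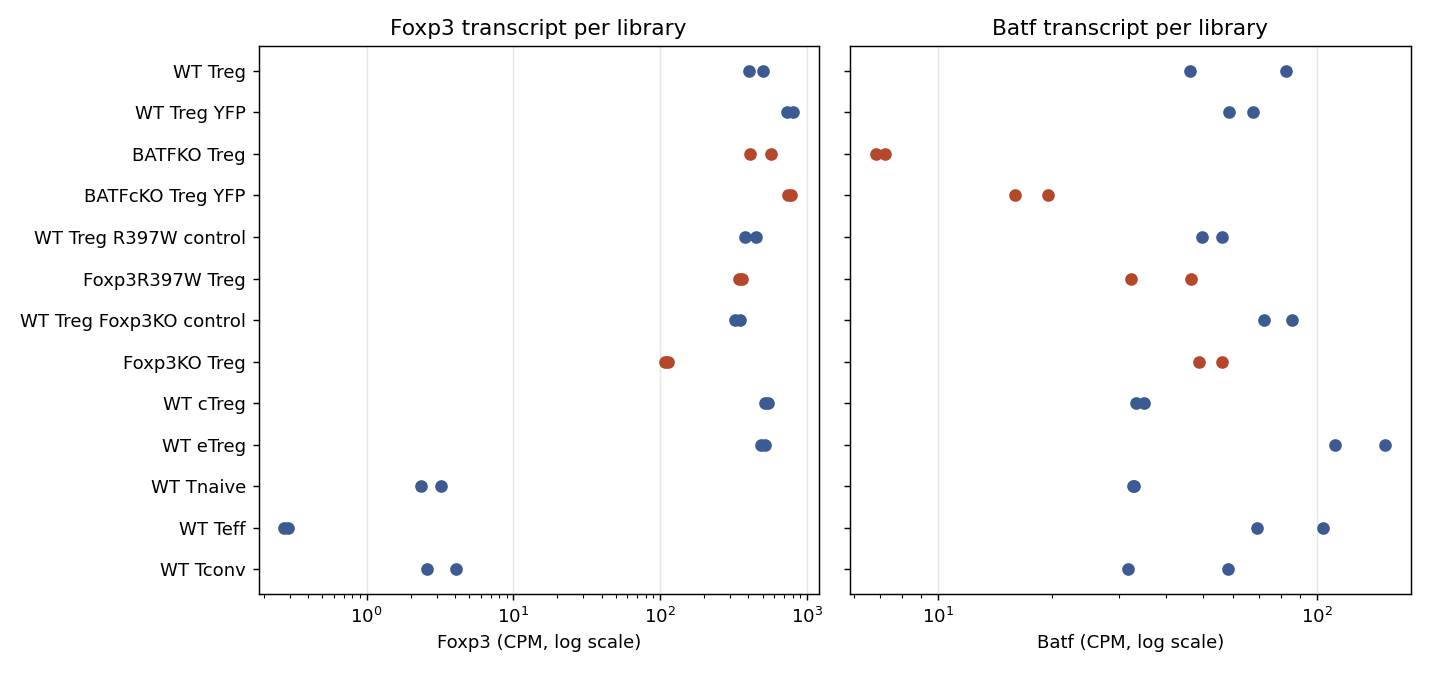
CPM of Foxp3 (left) and Batf (right) on log axes, 1 point per library and 2 libraries per group, with mutants in orange and WT groups in blue. Batf is at 7.02 CPM on average in BATFKO Treg and 17.7 in BATFcKO Treg YFP, and Foxp3 is at 111 CPM in Foxp3KO Treg.

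WT Treg were compared with Tconv and cTreg with Tnaive to see which genes mark the Treg lineage with and without effector cells in the gate. In cTreg, Lrrc32 (GARP, which presents latent TGF-beta) stood at 362 ± 11.2 CPM against 0.407 in Tnaive (9.77 ± 0.46), Il2ra (the high-affinity chain of the IL-2 receptor) at 658 ± 10.2 against 3.18 ± 0.971 (7.69 ± 0.33), and Foxp3 rose by 7.57 ± 0.22. Itgb8, an integrin that activates TGF-beta, was at least 57.41-fold higher in cTreg, and Peli2 and Dnah7a were at least 62.51-fold and 40.5-fold higher. Ntn4 had a count ratio of 319.6 (95% interval 56.96 to 12660) and Sdc4 of 176.7 (60.15 to 859.4). The inhibitory receptor Ctla4 rose by 4.73 ± 0.25, Il2rb by 5.16 and the Foxp3 partner Ikzf4 (Eos) by 3.68 ± 0.13. Lower in cTreg were Pdlim4 (0.525 against 78.1 ± 8.36 CPM), Klrd1 (-5.62 ± 0.58), Abhd15, App (1.17 against 49.2 CPM), Amz1, Atp8b4 (-4.51 ± 0.25), Adamts14 and Lrrc75b. The naive T cell regulators Tcf7 (1033 ± 9.49 against 2146 ± 112 CPM, -1.05 ± 0.11) and Lef1 (-1.13 ± 0.12) were also lower, whereas the lymph node homing gene Ccr7 (edgeR adjusted p = 0.33) was not called.

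Between cTreg and Tnaive 967 genes were called higher and 525 lower. All 20 tested Treg core genes were called higher, also adjusted over the list alone, with a median of 4.51 (camera adjusted p = 2.77e-155). Suppressor molecules had 9 called higher and 1 lower. Of the naive and central T cell genes 4 were called higher and 7 lower (4 and 8 adjusted over the list alone, median -0.06, camera adjusted p = 0.00686, adjusted p = 0.28 with an estimated correlation). In WT Treg against Tconv 1475 genes were called higher and 817 lower. There Lrrc32 rose by 10.05 ± 0.48, Foxp3 by 7.11 ± 0.22, Itgae by 6.06 ± 0.28 and Il1rl1 by 6.31 ± 0.68. The transporter gene Slc7a10 was at least 46.37-fold, Bicd1 at least 35.44-fold and Peli2 at least 29.53-fold higher, and Gbp2b had a count ratio of 187.8 (33.35 to 7453). Pdlim4 was at least 253.6-fold lower, and Zbtb16 had a count ratio of 121.9 (21.42 to 4859), Klrd1 of 100.5 (17.57 to 4012) and Adgrg5 of 42.89 (11.47 to 360.6) in favour of Tconv, with Atp8b4 at -5.70. Treg core genes were again all 20 called higher, also adjusted over the list alone (median 3.78, camera adjusted p = 5.94e-121). Effector Treg genes had 26 called higher and 1 lower (27 and 1 adjusted over the list alone). Fitted on the libraries of each comparison alone, 519 genes were called in WT Treg against Tconv and 2933 in cTreg against Tnaive. Without Tnaive 1 the cTreg comparison called 993 genes.

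Effector differentiation of Treg was measured by comparing eTreg with cTreg. The inhibitory receptor gene Klrg1 had a count ratio of 1376 (246.6 to 54390), with 66.4 ± 3.33 CPM in eTreg, and Il10, encoding a suppressive cytokine, had a ratio of 421 (75.15 to 16670). The long noncoding RNA Miat was at least 237.6-fold higher. The co-inhibitory receptor Tigit stood at 252 ± 61.2 against 1.01 CPM (7.94 ± 0.63), the chemokine receptor Cxcr3 at 164 ± 15.9 against 2.42 (6.08 ± 0.35), and Il1rl1, the receptor of the alarmin IL-33, at 111 against 3.44 (5.02 ± 0.44). The costimulator Icos rose by 3.27 ± 0.17, the transcription factor Maf by 4.83 ± 0.29 (726 ± 16.3 against 25.5 ± 5.24 CPM), and the integrins Itgae and Itgb1 by 4.51 ± 0.21 and 2.91 ± 0.14. Sostdc1, Ecel1, Srxn1, Ky, Lrrn3 and Mid2 were at least 81.75-fold higher, at a spread close to the mean for Ecel1 (16.6 ± 17.6 CPM) and Sostdc1 (27.3 ± 19.7). Genes of resting cells fell. Igfbp4 (-6.82 ± 0.23), the quiescence-linked regulators Satb1 (-3.57 ± 0.15) and Bach2 (-2.25 ± 0.11), and Sorcs2 (-5.87 ± 0.36) were lower in eTreg. The count ratio in favour of cTreg was 88.63 (24.17 to 737.6) for Acvr1c, 79.57 (21.66 to 662.7) for Ampd1 and 74.87 (25.29 to 365.8) for Dapl1. It was 66.98 (18.18 to 558.8) for Tmem108, 57.41 (19.32 to 281.1) for Drc1 and 53.71 (18.05 to 263.2) for Nrp2.

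Calls numbered 2302 higher and 1498 lower in eTreg, and 5851 in all when only these 4 libraries were fitted. All 31 effector Treg genes were called higher, also adjusted over the list alone (median 4.59, camera adjusted p = 2.61e-51), and 20 of the 22 naive and central T cell genes lower, also adjusted over the list alone (median -2.08, camera adjusted p = 2.64e-47). Suppressor molecules had 14 called higher and 2 lower (14 and 2 adjusted over the list alone, camera adjusted p = 5.94e-12). Of the 14 Th1 genes 10 were called higher and 1 lower (median 2.55 at the bound), of the 11 Th2 genes 10 and 1 (3.62 at the bound), and of the 9 Th17 genes 7 and 0 (3.13). Cell cycle genes had 10 called higher and 0 lower (12 and 0 adjusted over the list alone, camera adjusted p = 0.0487, adjusted p = 0.673 with an estimated correlation).

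Conventional activation was measured by Teff against Tnaive, and eTreg were set against Teff. The Th1 receptor Cxcr3 (9.66 ± 0.45), the chemokine Ccl5 (9.59 ± 0.43) and Itgb1 (4.31 ± 0.15) rose in Teff, and Ifng had a count ratio of 720.5 (128.9 to 28490). Klrb1c, Zbtb16, Cebpa, Serpina3f and Fgl2 were at least 688.4-fold, 571.7-fold, 321.3-fold, 251.4-fold and 235.5-fold higher. Klrb1c is among the CD8 and NK markers. Whether such rises came from activated conventional T cells or from other cells in the Teff gate was not tested. Igfbp4 (-6.95 ± 0.22), Sorcs2 (-6.06 ± 0.43), Ampd1 (-6.03 ± 0.47), Adamts14 (-5.75 ± 0.51), Tmem108 (count ratio 64.12, 17.37 to 535.6) and Lef1 (-2.53 ± 0.12) fell. Dendritic cell genes moved with Teff. Siglech had a count ratio of 1089 (195.1 to 43060) and a spread close to its mean (56.2 ± 51.2 CPM), and Mpeg1 stood at 98.9 ± 87.5 against 0.656 CPM. Calls numbered 2595 higher and 1717 lower. Myeloid and dendritic markers had 12 called higher and 1 lower (12 and 1 adjusted over the list alone, camera adjusted p = 0.000232, adjusted p = 0.0911 with an estimated correlation), and CD8 and NK markers 6 and 2 (6 and 2 adjusted over the list alone, camera adjusted p = 0.000167). B cell markers had 6 called higher and 1 lower (6 and 1 adjusted over the list alone), among them the MHC class II genes H2-Ab1 (4.76 ± 0.29) and Cd74 (4.08).

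Against Teff, eTreg had Foxp3 higher by 10.74 ± 0.28, Lrrc32 by 7.74 ± 0.41, Neb by 5.16 ± 0.40, Gbp2b by 4.74 ± 0.32, Slc7a10 by 4.73 ± 0.50, Itgae by 3.65 ± 0.20 and Il1rl1 by 3.61 ± 0.39, with Ky at least 86.64-fold higher, Ppp1r3fos at 4.83 and a count ratio of 48.73 (16.35 to 239.1) for Hgf. The Th1 regulators Tbx21 (-2.62 ± 0.27) and Eomes (-4.87 ± 0.42) and the cytokines Ifng (-2.31 ± 0.36) and Il2 (-4.44 ± 0.49) were lower. Of the largest falls Siglech was at least 382.2-fold, Aqp9 208.2-fold, Bcl11a 71.57-fold, Clec10a 46.95-fold, Adam23 45.64-fold, Esm1 41.7-fold and Epha2 36.12-fold lower in eTreg, and Sulf2 had a count ratio of 562.4 (100.5 to 22250). Calls numbered 1004 higher and 888 lower, but 872 higher and 947 lower without the expression filter. Treg core genes had 18 called higher and 0 lower (18 and 0 adjusted over the list alone, median 1.93), and Th1 genes 0 and 9 (0 and 10 adjusted over the list alone, median -0.94, camera adjusted p = 3.59e-10). Myeloid and dendritic markers had 0 and 9, and CD8 and NK markers 0 and 7. Whether other cells in the Teff gate contributed to the genes lower in eTreg was not tested. Activation of Treg and of conventional cells differed for 663 genes, 192 in the direction of Treg and 471 in the direction of conventional cells. Of the 663, 32 were at least 4-fold higher in both Teff libraries than in any other library. Without Teff 1, eTreg 1 or eTreg 2 the eTreg comparison called 1168, 1242 or 1179 genes, and without cTreg 2 the difference called 431.

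Germline loss of BATF was compared with WT Treg to see which Treg genes depend on it. Itgb1 (chromosome 8, 128685654 to 128733200), the beta-1 integrin of matrix and VCAM-1 adhesion, fell to 53.6 ± 11.3 from 425 ± 38.6 CPM (-2.98 ± 0.15, edgeR adjusted p = 6.3e-10). Itgae (chromosome 11, 73090583 to 73147446), the CD103 chain that binds E-cadherin on epithelium, fell to 18.5 ± 1.83 from 142 ± 7.01 (-2.94 ± 0.20, edgeR adjusted p = 1.4e-07). The skin and tissue homing receptor Ccr4 (-3.69 ± 0.37), the co-inhibitory receptor Tigit (6.78 against 87.5 ± 23.4 CPM, -3.66 ± 0.51), Icos (-1.21 ± 0.16), and the receptor genes Il18rap (-2.07 ± 0.21) and Ccr8 (-1.69 ± 0.26) fell as well. Ttc39c (-4.73 ± 0.35) and the regulator Tox2 (0.284 against 40.9 ± 26.9 CPM, -7.04 ± 0.84) were lower. Slc7a10 (chromosome 7, 35186385 to 35201114) was at least 52.63-fold lower. Counts favoured WT Treg by 205.2-fold (36.41 to 8143) for Cebpa (chromosome 7, 35119293 to 35121928), 59.84-fold (16.21 to 499.8) for the colon homing receptor Gpr15, 49.28-fold (16.53 to 241.7) for Ttbk1 and 29.5-fold (9.77 to 145.8) for Miat.

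Higher in BATFKO Treg were the vitamin D receptor Vdr (36.9 ± 14.3 against 3.18 ± 1.46 CPM, 3.49 ± 0.49), Plac8 (3.34 ± 0.43), Plagl1 (125 ± 15.8 against 37.1 ± 0.137, 1.76 ± 0.24), Fn1 (3.88 ± 0.57), Gja1 (4.34 ± 0.64), Pparg (3.49 ± 0.58), Igfbp7 (3.35 ± 0.61) and Ptrf (3.21 ± 0.44), and Lamb1 with a count ratio of 65.13 (17.67 to 543.5). Gja1, Lamb1 and Pparg varied widely, as in 9.35 ± 5.86 CPM for Gja1. Irf4, the partner of BATF on composite DNA sites, rose by 0.85 ± 0.12 (299 ± 16.9 against 165 ± 2.40 CPM, edgeR adjusted p = 0.00042). Interferon-induced Gbp2 (1.14 ± 0.14), Irf1 (0.63 ± 0.16) and Zbp1 (0.78 ± 0.15) rose. The suppressor gene Ctla4 was not called (-0.68 ± 0.19, edgeR adjusted p = 0.074).

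In BATFKO Treg 128 genes were called higher and 201 lower. Effector Treg genes had 11 of 31 called lower and 1 higher (15 and 3 adjusted over the list alone, median -0.74, camera adjusted p = 2.25e-19). Chemokine receptors and integrins had 6 of 26 lower and 0 higher (9 and 1 adjusted over the list alone, median -0.30, camera adjusted p = 9.26e-15). Interferon response genes had a median of 0.62 with 3 of 21 higher and 0 lower (14 and 0 adjusted over the list alone, camera adjusted p = 6.16e-15, adjusted p = 0.0675 with an estimated correlation). Th17 genes, with Rora (-1.50 ± 0.18) and Ahr (-0.80 ± 0.18) called, had a median of -1.25 and 3 of 9 lower (3 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.000175, adjusted p = 0.125 with an estimated correlation). For suppressor molecules, with 3 of 17 lower, the camera adjusted p = 0.000594 became an adjusted p = 0.172 with an estimated correlation. Tfh genes, with Icos and Bcl6 (-0.75 ± 0.18) among 4 called lower, went from 3.05e-05 to 0.127 in the same way. Treg core genes had 1 of 20 higher and 2 lower (2 and 4 adjusted over the list alone, median -0.03, camera adjusted p = 0.0512). The eTreg-high genes had 146 called lower and 36 higher (289 and 62 adjusted over the list alone), with a median of -0.36 (camera adjusted p = 1.31e-14, adjusted p = 0.0204 with an estimated correlation). The Treg-low list, with 6 called lower and 0 higher (17 and 4 adjusted over the list alone, median -0.41), passed only at the preset correlation (camera adjusted p = 0.000113, adjusted p = 0.0587 with an estimated correlation). So did the Treg-high list, with a median of -0.08 and 24 called lower and 17 higher (39 and 22 adjusted over the list alone, 0.00525 and 0.154), and the cTreg-high list, with 2 lower and 23 higher (3 and 27 adjusted over the list alone, 0.00307 and 0.298). Without BATFKO Treg 2 the cTreg-high median turned from 0.05 to -0.0989. As single libraries were left out, the Treg-low median ran from -0.62 to -0.13 and the eTreg-high median from -0.49 to -0.23. These calls depend on the model. Libraries of WT Treg and of BATFKO Treg varied more within a group than most others, so the shared spread may make these p-values too small. A block for library number, a pairing that the labels do not state, gave 1036 calls, so variation shared by such libraries could instead make these p-values too large. Fitted on the 4 libraries of this comparison alone, 2 genes were called, and without WT Treg 2 the full model called 176.

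Deletion of Batf in Foxp3-expressing cells asks whether its loss acts within Treg. Itgb1 (51.9 ± 0.195 against 377 ± 57.6 CPM, -2.86 ± 0.15, edgeR adjusted p = 1.4e-09), Itgae (27.9 ± 4.16 against 155 ± 19.6, -2.47 ± 0.20), Ccr4 (-3.33 ± 0.34), Tigit (1.91 ± 0.259 against 54.6 ± 6.25, -4.83 ± 0.64), Icos (62.2 ± 2.23 against 185 ± 29.2, -1.57 ± 0.17) and Cxcr3 (-1.98 ± 0.30) fell in BATFcKO Treg YFP. Klrg1, 24.2 ± 5.32 CPM in WT Treg YFP, had a count ratio of 144.2 (39.58 to 1195). The genes of the calcium-binding proteins S100a4 (-3.99 ± 0.30) and S100a6 (-2.81 ± 0.25), the IL-18 receptor chain Il18rap (-3.75 ± 0.25), Ccl5 (-2.94 ± 0.50) and Tox2 (-5.63 ± 0.95) fell. Rora, a regulator of tissue Treg, went from 91.5 ± 3.49 to 18.9 ± 0.339 CPM (-2.27 ± 0.20). Miat was at least 28.41-fold and Slc7a10 at least 23.27-fold lower and Cebpa changed by -4.87 ± 1.06. The count ratio in favour of WT Treg YFP was 143.7 (39.45 to 1192) for Ttc39c, 43.52 (14.6 to 213.5) for Gpr15 and 34.75 (11.6 to 171) for Plekhg3. Fewer genes rose, led by Plac8 (2.82 ± 0.46), Cyp26b1, which degrades retinoic acid (2.28 ± 0.52), Gbp2b (67.4 ± 10.4 against 18.0 ± 2.81 CPM, 1.91 ± 0.23), Tgm2 (1.48 ± 0.27), Prg4 (1.42 ± 0.32), Gbp11 (1.42 ± 0.24), Myo6 (1.26 ± 0.27) and Plagl1 (1.09 ± 0.25). The resting T cell gene Igfbp4 (499 ± 29.8 against 268 ± 28.8, 0.90 ± 0.17) and Myc (0.54 ± 0.11) rose too. The Treg genes Ikzf2 (555 against 924 CPM, edgeR adjusted p = 0.17) and Irf4 (0.33 ± 0.13, edgeR adjusted p = 0.29) were not called.

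Called genes numbered 39 higher and 210 lower in BATFcKO Treg YFP. DESeq2 called 83 higher and 285 lower, and a block for library number gave 471 and 644, so this balance depends on the model. Effector Treg genes had 15 of 31 called lower and 0 higher (25 and 1 adjusted over the list alone, median -1.50, camera adjusted p = 1.95e-62). Chemokine receptors and integrins had 10 of 26 lower and 0 higher (12 and 0 adjusted over the list alone, median -0.65 at the bound, camera adjusted p = 5.17e-26). Suppressor molecules had a median of -0.76 with 3 of 17 lower (7 adjusted over the list alone, camera adjusted p = 1.83e-08). Naive and central T cell genes had a median of 0.32 with 3 of 22 higher and 0 lower (6 and 0 adjusted over the list alone, camera adjusted p = 6.07e-11). Of the helper lineage lists, Th1 had a median of -0.62 with 5 of 14 genes lower (6 adjusted over the list alone, camera adjusted p = 1.04e-13) and Th2 of -0.98 at the bound with 3 of 11 lower (4 adjusted over the list alone, 1.85e-07). Th17 genes had a median of -0.86 at the bound with 2 of 9 lower (4 adjusted over the list alone, camera adjusted p = 6.75e-08) and Tfh genes of -0.72 with 4 of 14 lower (6 adjusted over the list alone, 1.12e-10). Treg core genes had 1 of 20 higher and 2 lower (2 and 4 adjusted over the list alone, median -0.00, camera adjusted p = 0.215). Dissociation stress genes had a median of 0.46 with 0 called by edgeR (camera adjusted p = 0.0024, adjusted p = 0.408 with an estimated correlation), among them Hspa1a at 8.26 against 0.597 CPM (edgeR adjusted p = 0.64), Hspa1b and Ier2. The eTreg-high genes had 194 called lower and 5 higher (432 and 13 adjusted over the list alone), with a median of -0.65 (camera adjusted p = 1.27e-50), and the cTreg-high genes 20 higher and 0 lower (34 and 0 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 4.92e-20). Leaving out a library left fewer calls, with 73 without BATFcKO Treg YFP 2, 93 without WT Treg YFP 2, 101 without BATFcKO Treg YFP 1 and 160 without WT Treg YFP 1.

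Between both BATF comparisons 20 genes were called higher in common (0.408 expected by chance, Fisher's exact p = 3.11e-30) and 102 lower (3.45 expected, Fisher's exact p = 1.11e-134), and 0 were called in opposite directions. Expected counts and p-values of overlaps, here and below, treat genes as independent and equally likely to be called, which they are not. They do not measure agreement between samples. Their difference was called by edgeR for 0 genes, with 633 at an unadjusted p below 0.05, and for 11 by DESeq2. With a block for library number, a pairing that the labels do not state, edgeR called 139. Equal effects were therefore not shown. The log2 changes correlated across genes with r = 0.497.

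Foxp3R397W Treg were compared with their WT control to see what Treg keep when Foxp3 carries a missense change. Whether the protein was present was not measured. Il17a (chromosome 1, 20730905 to 20734496), the signature cytokine of Th17 cells, rose to 53.0 ± 19.2 from 0.635 ± 0.465 CPM (6.37 ± 0.60, edgeR adjusted p = 3.6e-05). The Th17 gene Ccl20 (4.45 ± 0.57) and the helper cytokine Il21 (3.61 ± 0.67) rose, and Il17f had a count ratio of 25.86 (6.813 to 219). Higher too were Mstn (4.75 ± 0.72), Dlg2 (4.75 ± 0.60) and Myof (4.60 ± 0.61), with count ratios of 50.25 (13.56 to 420.5) for Cd163l1 and 35.12 (11.7 to 173) for Alpk2, and Lpar3 at least 28.29-fold. Tcf7 (1433 ± 52.1 against 771 ± 15.03 CPM, 0.89 ± 0.11), Lef1 (0.62 ± 0.12) and Satb1 (0.70 ± 0.13) rose. Among Treg genes, Lrrc32 fell to 99.0 ± 18.8 from 418 ± 32.4 (-2.08 ± 0.27), Nrp1, a marker of thymic Treg, to 118 ± 1.19 from 441 ± 5.47 (-1.90 ± 0.18), and Itgb8 (-2.67 ± 0.39) and the IL-35 subunit Ebi3 (-2.44 ± 0.34) fell. Effector genes fell as well, with Itgae at 13.4 ± 1.58 against 130 ± 6.46 CPM (-3.28 ± 0.21), Il1rl1 at 2.73 ± 0.697 against 54.5 ± 1.49 (-4.31 ± 0.49), Ccl5 at -4.01 ± 0.49, Itgb1 at -1.73 ± 0.14 and Klrg1 with a count ratio of 319.8 (56.97 to 12670). Slc7a10 had a ratio of 99.42 (17.43 to 3967), and Cebpa (-3.62 ± 0.80), Pcyt1b (-4.30 ± 0.47), Ces2c (-4.12 ± 0.79), Plekhg3 (-4.08 ± 0.59) and Nid2 (-4.05 ± 0.53) fell. Gata3, the Th2 regulator used by tissue Treg, changed by -0.89 ± 0.15.

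Calls numbered 267 higher and 482 lower in Foxp3R397W Treg. Treg core genes had 16 of 20 called lower and 0 higher, also adjusted over the list alone (median -1.02, camera adjusted p = 5.5e-33). Th17 genes had 7 of 9 higher and 0 lower (8 and 1 adjusted over the list alone, median 2.08, camera adjusted p = 1.26e-12), and Th2 genes 6 of 11 lower and 0 higher (7 and 0 adjusted over the list alone, median -1.55, camera adjusted p = 6.6e-09). Effector Treg genes had 11 of 31 lower and 2 higher (19 and 5 adjusted over the list alone, median -0.71, camera adjusted p = 4.28e-13), suppressor molecules 7 of 17 lower and 1 higher (11 and 2 adjusted over the list alone, median -0.81), and naive and central T cell genes 10 of 22 higher and 0 lower (12 and 1 adjusted over the list alone, median 0.35). Chemokine receptors and integrins had a median of 0.07 but a mean of -0.53, with 7 of 26 lower and 1 higher (9 and 4 adjusted over the list alone, camera adjusted p = 3.67e-05, lower). B cell markers had a median of -0.88, with 4 of 8 lower and 1 higher, also adjusted over the list alone, among them Cd22 (-2.72 ± 0.51), Cd74 (-2.40 ± 0.28) and Cd79b (camera adjusted p = 0.00157, adjusted p = 0.0985 with an estimated correlation). Erythroid markers, of which 2 were tested, had 0 called by edgeR (0 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0319, adjusted p = 0.154 with an estimated correlation). Cytokine genes had 3 of 14 higher and 2 lower (6 and 3 adjusted over the list alone, camera adjusted p = 0.0263, adjusted p = 0.139 with an estimated correlation). The Treg-high genes had 117 called lower and 1 higher (148 and 8 adjusted over the list alone), with a median of -0.97 (camera adjusted p = 1.01e-63), and the Treg-low genes 39 higher and 1 lower (51 and 2 adjusted over the list alone), with a median of 0.91 (camera adjusted p = 4.67e-39). Calls fell to 329 without control 3, 391 without control 4, 412 without mutant 1 and 378 without mutant 2, and rose to 1416 when only these libraries were fitted.

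Foxp3KO Treg, sorted by their reporter, show what cells that turn on the Foxp3 gene express when it carries a knockout allele. Again Il17a (14.8 ± 6.11 against 0.260 ± 0.0343 CPM, 5.78 ± 0.55), Il17f (4.33 ± 0.44) and Ccl20 (3.63 ± 0.53) rose. Ggt5 rose to 34.5 ± 2.99 from 3.58 ± 0.288 (3.27 ± 0.19), and Pde3b, which breaks down cyclic AMP, to 170 ± 19.6 from 29.1 ± 2.53 (2.54 ± 0.16, edgeR adjusted p = 1.7e-08). Pdlim4 (2.64 ± 0.42), Dsp (2.50 ± 0.32) and Lypd6b (2.30 ± 0.24) rose, as did Igfbp4 (1.22 ± 0.17), Tcf7 (1880 ± 19.7 against 1070 ± 6.89, 0.81 ± 0.11) and Bach2 (0.57 ± 0.10). Lrrc32 fell to 63.0 ± 9.08 from 300 ± 54.8 CPM (-2.25 ± 0.26), and Nrp1 (-1.80 ± 0.17), Itgb8 (-2.47 ± 0.32), Ebi3 (-2.48 ± 0.27) and Entpd1, encoding the ectonucleotidase CD39 (-1.30 ± 0.17), fell. Klrg1 (0.440 ± 0.260 against 21.7 ± 1.45, -5.60 ± 0.50), Il1rl1 (-3.20 ± 0.37), Itgae (15.3 ± 0.781 against 124 ± 2.53, -3.02 ± 0.19), Itgb1 (-1.42 ± 0.13), Rora (-1.14 ± 0.17) and the tissue repair factor Areg (-1.99 ± 0.48) fell. Further falls were in Slc7a10 (-5.21 ± 0.53), Noxa1 (-4.55 ± 0.43), Cebpa (-3.54 ± 0.53), Ccr3 (-3.46), Rin2 (-3.39 ± 0.35), Bicd1 (-3.31 ± 0.32) and Cdcp1 (-3.26 ± 0.24). Ctla4 was not called (849 against 1100 CPM, edgeR adjusted p = 0.31), nor was Mki67 (125 against 284, edgeR adjusted p = 0.12).

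Calls numbered 320 higher and 781 lower in Foxp3KO Treg in libraries deeper than those of the Foxp3R397W set, and 615 in all when thinned to that depth. Treg core genes had 17 of 20 called lower, Foxp3 itself among them, and 0 higher (18 and 0 adjusted over the list alone, median -1.01, camera adjusted p = 6.36e-29). Effector Treg genes had 19 of 31 lower and 0 higher (21 and 1 adjusted over the list alone, median -1.08, camera adjusted p = 2.58e-20), suppressor molecules 10 of 17 lower and 0 higher (11 and 0 adjusted over the list alone, median -1.30), and naive and central T cell genes 13 of 22 higher and 0 lower (14 and 1 adjusted over the list alone, median 0.57). Th17 genes had 5 of 9 higher and 1 lower, also adjusted over the list alone (median 1.78, camera adjusted p = 2.77e-06, adjusted p = 0.0566 with an estimated correlation), and Th2 genes 7 of 11 lower and 0 higher, also adjusted over the list alone (median -1.23). Cell cycle genes, including Ccnb2 (-1.22 ± 0.29), Tyms (-0.96 ± 0.23), Plk1 and Cdc20, had 9 of 24 lower and 0 higher (14 and 0 adjusted over the list alone, median -0.79, camera adjusted p = 3.43e-06, adjusted p = 0.222 with an estimated correlation). The bZIP and IRF factors had 1 of 17 higher and 0 lower (camera adjusted p = 0.827), and TCR signalling and immediate early genes 0 of 18 higher and 1 lower (camera adjusted p = 0.323). The Treg-high genes had 135 called lower and 0 higher (166 and 1 adjusted over the list alone), with a median of -0.93 (camera adjusted p = 1.35e-70), the Treg-low genes 50 higher and 2 lower (61 and 2 adjusted over the list alone), with a median of 0.84, and the eTreg-high genes 569 lower and 49 higher (790 and 69 adjusted over the list alone), with a median of -0.73 (camera adjusted p = 1.27e-50). Calls fell to 693 without control 5, 417 without control 6, 601 without Foxp3KO 1 and 418 without Foxp3KO 2, and rose to 4121 when only these libraries were fitted, with 1933 higher and 2188 lower, so that the balance between rises and falls depends on the model.

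Both Foxp3 comparisons shared 170 genes called higher (6.99 expected) and 379 lower (30.8 expected), with 0 in opposite directions. Their difference was called for 2 genes by edgeR (407 at an unadjusted p below 0.05) and 3 by DESeq2. Ccl5 fell in Foxp3R397W, to 0.845 ± 0.160 from 13.8 ± 2.81 CPM, and was not called in Foxp3KO, at 46.0 ± 0.929 against 52.5 ± 7.01 (difference 3.82 ± 0.56, edgeR adjusted p = 0.023). Foxp3 itself differed by -1.36 ± 0.21 (edgeR adjusted p = 0.023). When any 1 of the 8 libraries was left out, edgeR called 0 genes.

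**Figure D2:**
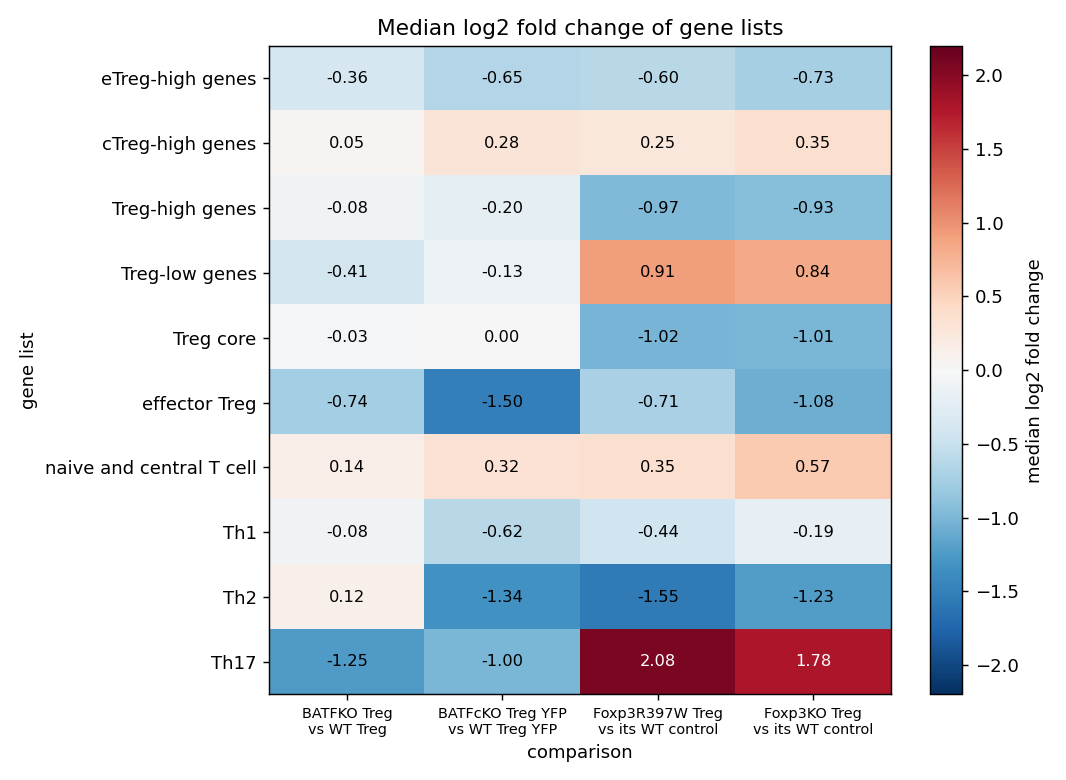
Median log2 fold change of 10 gene lists in the 4 mutant comparisons, as a heat map with lower values in blue and higher values in red. Values are fitted, and at the bound the BATFcKO medians of Th2 and Th17 are -0.98 and -0.86. The eTreg-high and effector Treg lists have negative medians in all 4 (eTreg-high -0.36, -0.65, -0.60 and -0.73), whereas Treg core medians are -1.02 and -1.01 in the Foxp3 mutants against -0.03 and -0.00 in the BATF mutants, and Th17 medians have opposite signs.

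The Foxp3 and BATF mutants were set side by side to ask which genes change with the loss of either factor. BATFcKO and Foxp3KO Treg shared 147 genes called lower (13.4 expected by chance) and 9 higher (1.02 expected), with 14 in opposite directions, and BATFcKO and Foxp3R397W shared 94 lower (8.28 expected) with 16 opposite. BATFKO shared 104 lower with Foxp3KO and 72 with Foxp3R397W, with 34 and 36 opposite. In all 4 comparisons 46 genes were called lower and 2 higher, Ddr1 and Gbp11. The following were picked from the 46 after their values were seen, in the order BATFKO, BATFcKO, Foxp3R397W and Foxp3KO. Alox8 changed by -3.33, -4.11, -3.26 and -3.09, the receptor kinase gene Axl by -0.93, -1.29, -2.09 and -2.41, and the adhesion receptor Cd44 by -0.83, -1.05, -0.53 and -0.47.

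Differences between a Foxp3 and a BATF comparison, tested after the data had been seen, separated the lists. Treg core genes were lower in Foxp3 mutants by a median of -0.77 (Foxp3R397W against BATFKO), -0.89 (Foxp3R397W against BATFcKO), -0.92 (Foxp3KO against BATFKO) and -0.92 (Foxp3KO against BATFcKO), with a camera adjusted p of at most 8.2e-05 under an estimated correlation. Treg-high genes were lower by -0.84, -0.64, -0.84 and -0.65 and Treg-low genes higher by 1.45, 1.03, 1.22 and 0.93 in the same order. Th17 genes were higher by 3.90, 3.66, 3.07 and 2.83 in the same order, with camera adjusted p = 0.00365, 0.00256, 0.0255 and 0.0108 under an estimated correlation. Differences of the eTreg-high list were -0.25, 0.07, -0.37 and -0.05. At the preset correlation those against BATFKO passed (camera adjusted p = 0.0106 for Foxp3R397W and 2.17e-07 for Foxp3KO) and those against BATFcKO did not (0.124 and 0.538), and none of the 4 passed with an estimated correlation (0.418, 0.654, 0.127 and 0.824). The effector Treg list differed by -0.14, 0.36, -0.18 and 0.15. Foxp3R397W lay above BATFcKO for this list at the preset (camera adjusted p = 2.94e-09) and with an estimated correlation (0.0353). The differences of Foxp3KO from BATFKO and BATFcKO passed at the preset correlation only (0.0321 and 0.000104, against 0.396 and 0.141), and that of Foxp3R397W from BATFKO at neither (0.905 and 0.958). Across genes, the change from cTreg to eTreg correlated with the mutant changes at r = -0.323 in BATFKO, -0.567 in BATFcKO, -0.344 in Foxp3R397W and -0.504 in Foxp3KO, over groups that share no library.

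**Figure D3:**
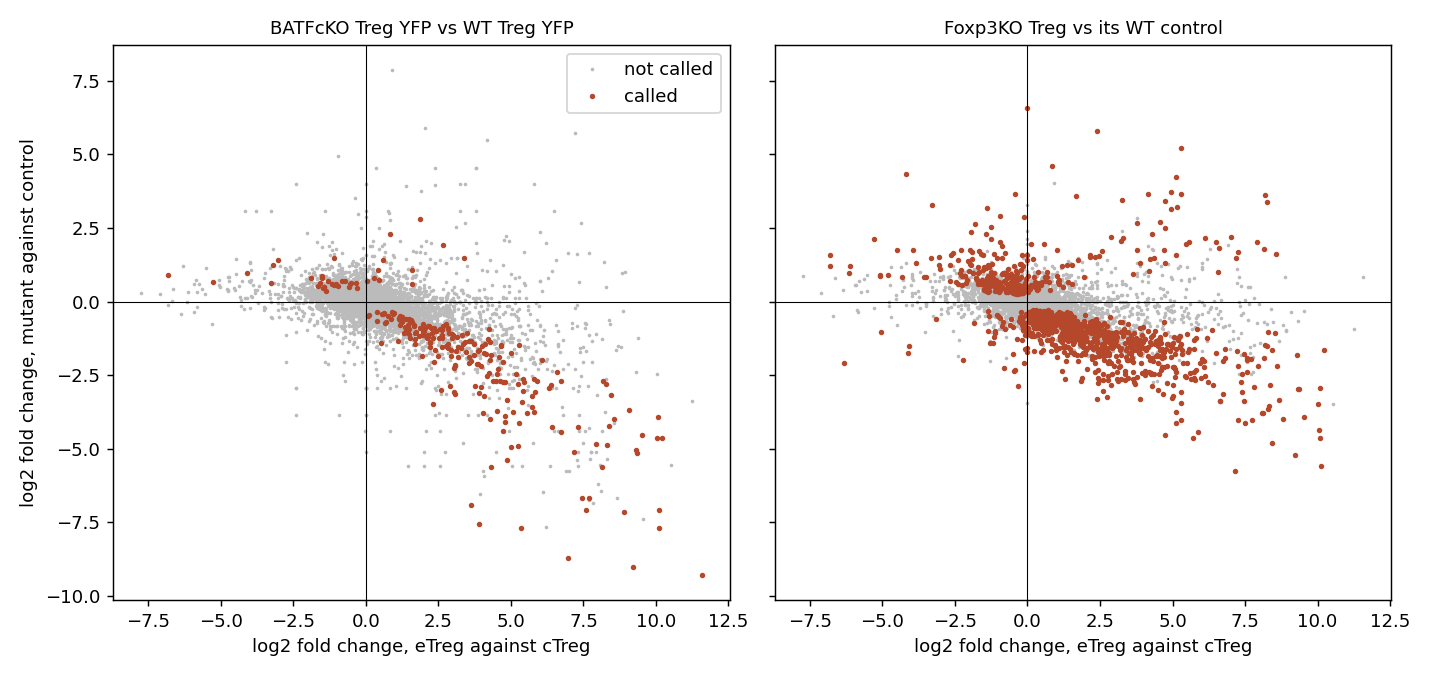
Log2 fold change per gene in BATFcKO against WT Treg YFP (left) and in Foxp3KO Treg against their WT control (right), plotted against the log2 fold change of eTreg against cTreg, with genes called in the mutant in orange and other tested genes in grey. Genes higher in eTreg lie mostly below 0 in both mutants (r = -0.567 and -0.504 across genes), and points far from 0 include genes at 0 reads in a group, whose fitted values are no bounds.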

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

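The test of sequencing depth was planned before its result was seen. The other tests in this part, on the share of eTreg and on dendritic and B cells, were chosen after the results were seen.

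A difference between the effects of both Foxp3 alleles was called by edgeR for 2 genes, Ccl5 (3.82, lower in Foxp3R397W Treg and not called in Foxp3KO Treg) and Foxp3 (-1.36, lower in Foxp3KO Treg). The WT controls also differed in Ccl5, with 52.5 CPM in the Foxp3KO set and 13.8 in the Foxp3R397W set. Whether the Ccl5 difference stems from the alleles or from the sets was not tested. When any 1 of the 8 libraries was left out, 0 genes were called. The Foxp3 difference is one of transcript, which fell in Foxp3KO Treg (111 against 337 CPM) and was not called in Foxp3R397W Treg (351 against 416). Why the transcript fell was not tested.

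The change from resting to effector cells differed between Treg and conventional cells for 663 genes, and for 431 without cTreg 2. The largest differences towards Treg were in Alox8 (3.95), which rose in eTreg, Nav2 (3.24), Abhd15 (3.22), Myo10 (3.20) and Foxp3 (3.17). Myo10 fell from 76.3 CPM in Tnaive to 5.56 in Teff, whereas it stood at 7.85 in cTreg and 5.27 in eTreg. Foxp3 did not rise in eTreg (503 against 530 CPM in cTreg), and its difference comes from 0.283 CPM in Teff against 2.77 in Tnaive. The largest towards conventional cells were Ly6d (-8.38), Peli2 (-8.50), Prr5l (-8.61), Aqp9 (-10.23) and Adam23 (-10.91), each with a group near 0 reads, so these fitted values are no bounds. Ly6d, at 18.4 CPM in Teff and 0.607 in Tnaive, is also in the plasmacytoid dendritic list tested below. Whether these changes arose in conventional T cells was not tested. Aqp9 stood at 30.1 ± 8.53 CPM in Teff and 1.41 in Tnaive.

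Dendritic cell genes were high in Teff alone among the sorted populations. Plasmacytoid dendritic cells in the Teff gate are a candidate source. Of 16 detected marker genes, 14 (87.5%, against 3.57% if all libraries were alike) had both Teff libraries above the other 6, the exceptions being Lair1 and Bst2. The share of all genes that do so was not computed, and the list includes Siglech and Mpeg1, already seen to be high in Teff. Of the 14, Siglech (56.2 ± 51.2 CPM), Mpeg1 (98.9), Irf8 (110), Ccr9 (97.2) and Pld4 (38.0) were the most abundant, while Bst2 stood at 76.6 CPM in Teff and 54.6 to 72.3 in the other sorted populations, and Irf8 and Ccr9 are also expressed by T cells. These cells can carry CD4. The labels of the Teff gate name no dendritic cell marker, and whether the gate removes such cells was not tested. B cells were argued against, as 1 of 7 detected B cell genes (14.3%) had both Teff libraries highest. The source of the CD8 and NK markers that were higher in Teff was not tested.

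Genes higher in eTreg than in cTreg were lower in the mutants, and fewer eTreg in the sorted pool could lower them together. To ask whether a lower share could be the whole cause, a mixture of eTreg and cTreg was fitted. A change of share fixes how far each eTreg-specific gene can fall from its cTreg and eTreg levels. Of these genes 32.0% in BATFcKO (31 of 97, 13 below and 18 above the fitted curve), 52.4% in BATFKO (55 of 105), 44.2% in Foxp3KO (50 of 113) and 47.1% in Foxp3R397W (48 of 102) differed from the best fitting mixture. A first version of this test, which assumed 1 common shift, gives 41.2%, 53.3%, 40.7% and 48% in the same order and was replaced because moderately specific genes need not fall alike, and the range of shares was then widened to 0. Fitted shares went from 8% to 0% in BATFcKO, from 6.5% to 1% in BATFKO and from 18.5% to 4.5% in Foxp3KO. In Foxp3R397W they went from 99.5% to 35.5%, so they are no measure of the real share. The eTreg to cTreg ratios entered without their own error, came from another set of libraries and rest in part on few cTreg reads. The test therefore cannot decide whether a lower share is the whole cause. A lower share as part or whole of the cause, changes among eTreg subsets and a direct effect on the genes all stay open.

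More genes were called in Foxp3KO (1101) than in Foxp3R397W Treg (749), in libraries of unlike depth. Thinned to the depth of the Foxp3R397W set, the Foxp3KO set gave a median of 615 calls (611 to 647), so deeper sequencing may account for the whole excess. A difference in strength between the alleles beyond that was not shown.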

How the results depend on the processing

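The thinned Foxp3KO set and the counts without Teff-specific genes were chosen after the data were seen. No result below had its cause tested unless it is given. No named gene changed direction where it was called in the main model or under the alternative. Changes of direction among genes called in neither were not counted. Under RLE scaling 1140 named results kept their side of the threshold, 4 gained and 1 lost a call. The counts were 1051, 2 and 2 with the stricter filter, 1093, 32 and 20 without a filter, 1054, 84 and 4 with DESeq2, 870, 177 and 98 with own libraries only, 728, 157 and 7 with the block, and 4991, 72 and 341 over all libraries left out in turn. RLE scaling changed the call of 2 of 171 tests of known lists, 1 gained and 1 lost.

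Restricting calls to at least 2-fold, which lowers counts by construction, left 217 in BATFKO, 422 in Foxp3R397W, 585 in Foxp3KO, 1930 in eTreg against cTreg, 2288 in Teff against Tnaive, 812 in cTreg against Tnaive, 1035 in eTreg against Teff and 1197 in WT Treg against Tconv. The overlap of BATFcKO with Foxp3KO went from 156 to 102 genes and that of both Foxp3 comparisons from 549 to 307.

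With an estimated correlation 65 of the tests of known lists passed in place of 101. In BATFKO the cTreg-high (0.0527, limma camera adjusted p = 0.298), Treg-high (-0.0793, 0.154) and Treg-low lists (-0.41, 0.0587) no longer passed.

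Fits on own libraries only, with fewer residual degrees of freedom and a spread of their own, called 2 genes in BATFKO, 378 in BATFcKO, 1416 in Foxp3R397W, 4121 in Foxp3KO, 5851 in eTreg against cTreg, 2933 in cTreg against Tnaive, 519 in WT Treg against Tconv, 7 between the Foxp3 alleles and 1174 between Treg and conventional activation.

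A block for library number gave 1036 in BATFKO, 1115 in BATFcKO (471 higher and 644 lower, against 39 and 210), 5973 in eTreg against cTreg, 6486 in Teff against Tnaive, 2897 in cTreg against Tnaive, 3609 in eTreg against Teff, 4168 in WT Treg against Tconv, 139 in conditional against germline BATF loss and 1641 between Treg and conventional activation. Deviations from the group means in libraries with the same number correlated in the germline set (r across genes 0.557, 0.571 and 0.495), less in the YFP set (0.242) and least in the 4 sorted populations (0.0801 to 0.233). The labels do not say that such libraries belong together, so the blocked counts were not taken as results.

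The difference between conditional and germline BATF loss gave 6 genes without a filter and 11 with DESeq2 in place of 0. DESeq2 called 83 genes higher and 285 lower in BATFcKO. Foxp3KO calls went from 1101 to 615 when thinned, through fewer reads. Teff-specific genes, 103 in all, were at least 4-fold higher in both Teff libraries than in any other library. Setting them aside without a new fit left 4209 calls in Teff against Tnaive, 1789 in eTreg against Teff and 631 between Treg and conventional activation. All 103 had been called in Teff against Tnaive and in eTreg against Teff. Those falls are therefore fixed by subtraction and do not test whether other cells drive the calls.

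Leaving out 1 library at a time, which leaves fewer samples, gave 176 (without WT Treg 2) to 355 calls in BATFKO, 73 (without BATFcKO Treg YFP 2) to 160 (without WT Treg YFP 1) in BATFcKO, 329 (without control 3) to 412 (without mutant 1) in Foxp3R397W, and 417 (without control 6) to 693 (without control 5) in Foxp3KO. The values between were 93 without WT Treg YFP 2, 101 without BATFcKO Treg YFP 1, 391 without control 4, 378 without Foxp3R397W 2, 601 without Foxp3KO 1 and 418 without Foxp3KO 2. Conditional against germline loss ran from 0 to 23 (without BATFKO 2), with 1 without WT Treg 2, and the Foxp3 alleles gave 0 each time. Other ranges were 993 (without Tnaive 1) to 1043 for cTreg against Tnaive, 431 (without cTreg 2) to 602 for Treg and conventional activation, and 1168 (without Teff 1) to 1467 for eTreg against Teff, with 1242 and 1179 without eTreg 1 and 2. Counts stayed within 1.5 times for eTreg against cTreg (2679 to 3017), Teff against Tnaive (3274 to 3504) and WT Treg against Tconv (1916 to 2081).

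In BATFKO the cTreg-high median reversed to -0.0989 without BATFKO 2, no longer passing, and reached 0.166 without BATFKO 1, and did not pass without WT Treg 2 (0.0634). The Treg-high median ran from -0.193 to -0.0639 and did not pass without BATFKO 2, and the Treg-low median from -0.621 to -0.126, not passing without BATFKO 1 (-0.126). The eTreg-high median kept its direction and call in all 4 mutant comparisons whichever library was left out (-0.49 to -0.23 in BATFKO, -0.70 to -0.58 in BATFcKO, -0.74 to -0.52 in Foxp3R397W, -0.83 to -0.63 in Foxp3KO). In the libraries of 5615929 to 7300917 counts, genes at 0 reads in a group allow only bounds. At a spread shared by all groups, 71%, 70% and 76% of simulated 2-fold changes were called in BATFKO, BATFcKO and Foxp3R397W. Smaller differences can be missed, and possibly more so in BATFKO, whose libraries varied more within groups.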

Other observations

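The test near Batf was planned before its result was seen, and the test on genes lower in all 4 mutant comparisons was chosen after.

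The neighbours Cebpa and Slc7a10 on chromosome 7, picked after their values were seen, were both called lower in all 4 mutant comparisons. Cebpa had a count ratio of 205.2 (36.41 to 8143) in favour of WT Treg over BATFKO, and changed by -4.87 in BATFcKO, -3.62 in Foxp3R397W and -3.54 in Foxp3KO Treg. Slc7a10 was at least 52.63-fold and 23.27-fold lower in BATFKO and BATFcKO. In the sorted populations Slc7a10 stood at 35.4 CPM in eTreg against 1.31 in Teff, while Cebpa was abundant in Teff too (48.0 ± 25.7 CPM, against 0 reads in Tnaive).

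Pdlim4 and Abhd15, which stood higher in Tnaive than in cTreg (78.1 against 0.525 CPM for Pdlim4), rose in Foxp3KO Treg by 2.64 ± 0.42 and 2.06 ± 0.32. Both genes are in the Treg-low list, and that list had a median of 0.84 in Foxp3KO and 0.91 in Foxp3R397W Treg.

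Genes lower in all 4 mutant comparisons may be mostly genes of the eTreg state. Of the 46 such genes 45 (97.8%) were eTreg-high, against 65.8% of the genes lower in 1 to 3 comparisons (one-sided Fisher's exact p = 1.81e-07). By the number of comparisons the share was 6.87% at 0, 59.7% at 1, 67.2% at 2 and 95.5% (84 of 88) at 3. Genes lower in all 4 thus hardly differed from those lower in 3. Expression level and statistical power differ between these sets and were not matched.

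DNA of the strain in which Batf was targeted could remain around the gene and change its neighbours in germline BATFKO Treg. Within 10 Mb of Batf, 3 of 107 tested genes were called (2.80%), namely Plekhg3, Tgfb3 and Ston2, against 316 of 11652 elsewhere (2.71%, one-sided Fisher's exact p = 0.558). So few calls near Batf neither show nor exclude such an effect. Plekhg3 was also called in the other 3 mutant comparisons, of which the Foxp3 comparisons have an intact Batf.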
